A study of Mus musculus with 4 samples.

How the data were processed

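Total RNA of IMS/N mouse hepatic stellate cells was measured in 4 groups of 1 sample each, namely untreated, IL17A, ADSC medium, and both, as the sample titles give them. Per the labels' protocols, RNA was labelled with Cy3 by a linear amplification kit, and per the file headers each array was an Agilent mouse design scanned in 1 colour and read with Feature Extraction, with probe positions on mm9. The deposited intensity values are linear processed signals, background-subtracted and detrended within each array per the file headers, and not normalized between arrays. Mean and background intensity columns deposited beside them were used for an alternative. The deposited score columns are flags of 0 or 1 for spots well above background, saturated or outlying, per the file headers. Quantile normalization was done by the authors per the series design text, after the stage of the deposited signals, and R 3.5.1 is named in the submitters' processing notes. Their 2 gene lists hold probe IDs, and the threshold behind them is not given in the sources used here. Doses and times of IL17A and medium are not given there either.

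Log2 processed signals were quantile normalized over the 4 arrays after control spots and outlier spots (126, 91, 107 and 100 per array) were left out. No spot was saturated. Spots of a probe were averaged. Of 41174 probes, 28696 were named through a RefSeq accession in the GRCm38.p6 gene table, 5761 by a current symbol in the file, 163 by an older symbol, and 6554 kept the file's name. A gene took its probe with the highest mean, which gave 26683 genes, 16667 of them well above background on at least 1 array. A gene counted as higher or lower when the log2 difference was 1 or more in size and its probe was well above background on the brighter array. A dim side was set to the higher of its own value and the lowest value well above background on that array, and such differences are given as "at least N-fold". That lowest value was taken over all probes of the array, so it is not the detection limit of the gene's own probe.

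Genes were named by a rule fixed before the data were examined. Per comparison it took the 10 largest differences in each direction among genes past the size rule and well above background on both arrays, without clone, accession and predicted names and without genes whose probes disagreed in direction. It added up to 4 members of each fixed list with the largest difference, or 8 for IL-17 targets, activation genes and collagens, the receptors Il17ra and Il17rc, and up to 5 bounds per direction. From each of these parts the text takes fewer genes, chosen from the largest down, with the exception of a single gene that the rule names and that is not reported here. The 30 gene lists, the comparisons and the alternatives were fixed at the same point. A list median took members well above background on both arrays and was ranked among 10000 random lists of the same size matched on mean level, for lists of 5 or more. Extreme ranks were common. For IL17A against untreated, 6 of 27 ranked lists lay at or below percentile 2.5 and 6 at or above 97.5. For IL17A plus medium against medium, 8 and 5 of 26 did. A rank thus sets a list beside randomly drawn genes on the same 2 arrays and is not a test.

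The number of arrays limits the precision. Spots of replicated probes gave a technical SD of a log2 difference of 0.30 below a log2 level of 5, 0.14 from 5 to 7 and 0.085 above. It holds no variation between cultures or RNA samples. A larger estimate from the differences of differences was 0.43, 0.26 and 0.11. Among genes past the rule with several measured probes, all probes went the same way in 90.1% for IL17A against untreated and 84.5% for medium added to IL17A.

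The additive fit used lmFit and eBayes with a trend in limma 3.58.1 (R 4.3.3) on genes well above background on at least 2 arrays, with Benjamini-Hochberg adjustment. Other steps used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1. Both were tested on simulated data for IL17A against untreated with 200 changed genes. The size rule recovered 95 of 100 genes changed 2.83-fold and 100 of 100 changed 8-fold among 15294 genes, with 74 false calls. The limma fit recovered 98 and 100 among 15472 genes, but 43 of its 241 calls were false, or 17.8%, above the nominal 5%. Its noise stepped between level classes. A second simulation with the spread interpolated over level, made after that was seen, left 15 false among 213 calls, or 7.04%. Adjusted p-values of the fit are therefore approximate.

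Alternatives covered 75th percentile and median scaling, normexp background correction with an offset of 50, stricter and no filters on dim probes, the mean of probes, 1.5-fold and 4-fold thresholds, eBayes without a trend, and list medians with members at their bound. A further alternative, probes matched to a RefSeq accession only, was added after a separate cloud of probes was seen in the plot of IL17A differences. Slide could not be fitted as a block, since each slide held the arrays of 1 medium condition.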

Results

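The study asked what medium conditioned by adipose tissue-derived stem cells (ADSC medium) does to hepatic stellate cells exposed to the cytokine IL17A. The cells were IMS/N, an SV40-immortalized line of stellate cells from the liver of a normal 129/Sv mouse. Stellate cells store vitamin A in the healthy liver and turn into matrix-producing myofibroblasts during fibrosis. Total RNA from 4 cultures was measured on 1-colour Agilent mouse arrays, with 1 array each for untreated cells, cells with IL17A, cells with ADSC medium and cells with both. Of 43379 non-control spots per array, 60.4% were well above background in untreated cells, 58.1% with IL17A, 59.8% with ADSC medium and 60.5% with both. Because each group had 1 array, no difference between groups has a replicate check, and "higher" and "lower" below describe 2 arrays. The untreated and IL17A arrays lay on slide 1 and both medium arrays on slide 2, so IL17A was compared within a slide and the medium only across slides.

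IL17A was set against untreated cells to describe the response to the cytokine alone. Il6, which encodes an inflammatory cytokine, was 108-fold higher with IL17A, going from a log2 level of 5.04 to 11.80. The neutrophil-attracting chemokines Cxcl5 and Cxcl1 were 51.8-fold and 38.3-fold higher, and the complement gene C3 was 43.8-fold higher. The acute-phase gene Saa3 and the iron-binding lipocalin Lcn2 were not well above background in untreated cells and were at least 142-fold and 50.5-fold higher. Regulators of IL-17 signalling were higher too, namely Zc3h12a by 4.05, Nfkbiz by 3.74 and Cebpd by 3.68 on the log2 scale. The probes lay, on the mm9 build, at chromosome 5, 30346362 to 30346421 for Il6, chromosome 5, 91190205 to 91190264 for Cxcl5, chromosome 5, 91321845 to 91321904 for Cxcl1 and chromosome 7, 53968031 to 53968090 for Saa3. Other genes high on the IL17A array were Urah (log2 difference 6.22, from a probe without a RefSeq accession), Gstt4 (4.48), the zinc transporter gene Slc39a4 (4.33), Sprr2h (4.26) and the proteoglycan gene Dcn (4.12). Ankk1, Nos2 and Csf3, also dim without IL17A, were at least 28.9-fold, 14.5-fold and 10.1-fold higher.

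Among named genes above background on both arrays, the lowest with IL17A were the organic anion transporter gene Slco2b1 (-3.86), the calcification inhibitor Mgp (-3.78), Klhl30 (-3.41) and Fam209 (-3.38). Lamb3 (-2.63), Misp3 (-2.36), Lrrc17 (-2.33), Ogn (-2.31) and Itga11 (-2.28) followed. Plg was at least 35.9-fold lower and was not well above background with IL17A. Among growth factors, Angpt1 was at -2.65 by its brightest probe and 0.36 by another, Igf1 at -1.92 and Fgf7 at 1.80. In all, 345 genes were at least 2-fold higher and 363 at least 2-fold lower among 15802 measured. The split was 263 higher to 533 lower with 75th percentile scaling and 263 to 532 with median scaling, and 97 and 66 with normexp background correction.

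Of the IL-17 target genes, 17 of 23 members above background on at least 1 of the 2 arrays were at least 2-fold higher and 0 were at least 2-fold lower. The 16 members above background on both arrays had a median difference of 1.78, above each of 10000 matched random lists. The receptor genes themselves were near their untreated levels, with -0.096 for Il17ra and -0.28 for Il17rc, while the adaptor gene Traf3ip2 was higher by 1.05. Stellate activation and myofibroblast genes had a median of -0.20, at percentile 0.04 of 10000 matched random lists. Periostin (Postn, -1.81), Ccn2 (-1.25) and Myl9 (-1.22) were lower, and 0 of the 20 measured members were at least 2-fold higher. Collagen genes had a median of -0.36, below each of 10000 matched random lists, with -0.88 for Col1a1 and -0.90 for Col1a2, and none of the 15 measured collagen genes passed the 2-fold rule. Among matrix proteases, Mmp3 (1.76), Mmp19 (1.37), Adamts4 (1.18) and Adamts9 (1.12) were higher. The list of proteases and inhibitors had a median of 0.16, with 9 of 18 members above 0 and 9 below. Glycolysis and hypoxia genes had a median of 0.45, above each of 10000 matched random lists, with Adm at 0.87 and Vegfa at 0.86. None of their 21 measured members passed the 2-fold rule. Antigen presentation genes had a median of -0.34, at percentile 0.05 of 10000 matched random lists. NF-kB feedback and inflammatory genes had a median of 0.40, above each of 10000 matched random lists, with 18 of 22 above 0. TGF-beta response genes had a median of -0.20, at percentile 0.09 of 10000 matched random lists. The apoptosis genes Fas and Bcl2l11 were higher by 2.80 and 1.51. Mitosis genes had a median of 0.029 and housekeeping genes a median of 0.0022.

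**Figure D1:**
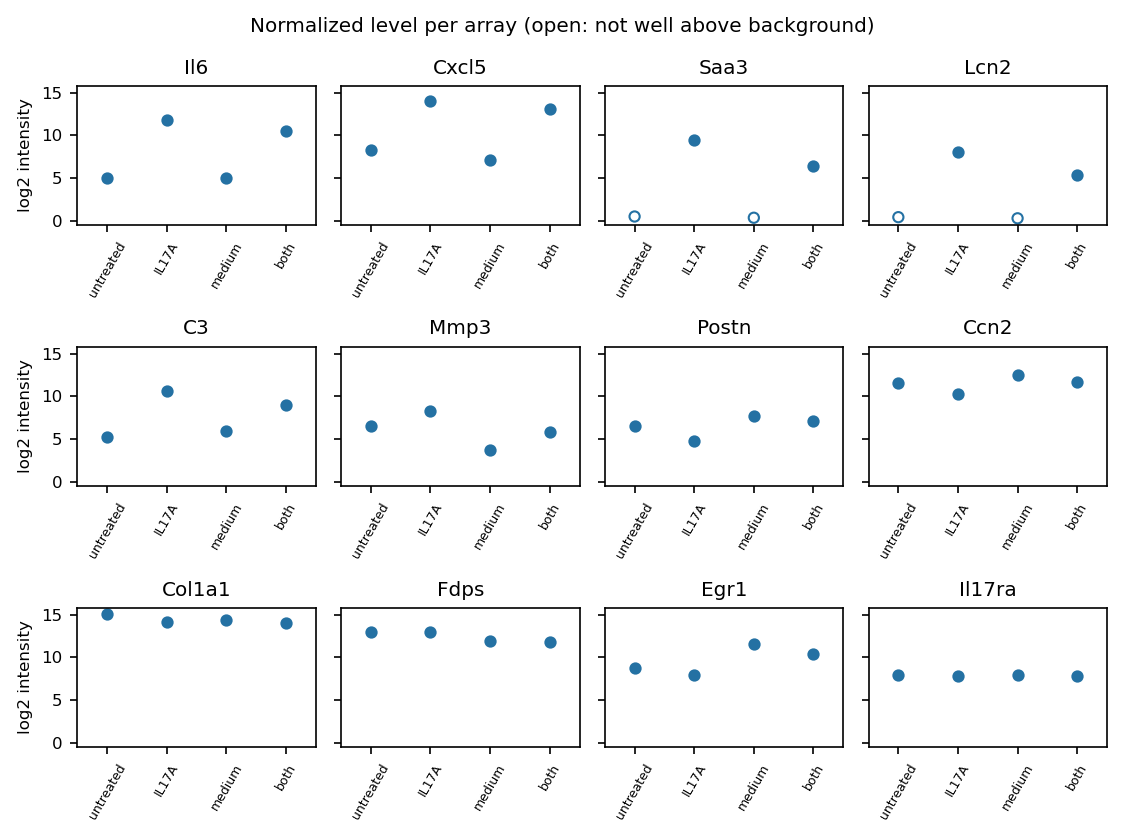
Normalized log2 intensity of 12 genes (vertical axis) on each of the 4 arrays (horizontal axis), with filled points well above background and open points not. Saa3 and Lcn2 were open in both groups without IL17A, and Il6 lay at 5.04 in untreated cells and 11.80 with IL17A.

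The response to IL17A was measured again in cells that had ADSC medium, within slide 2. Cxcl5 was 60.3-fold higher, Il6 44.7-fold, Cxcl1 41.7-fold, Urah (by the same probe) 21.8-fold and Zc3h12a 15.6-fold. Nfkbiz (3.60), Cebpd (3.38), Dcn (3.09) and the alarmin gene Il33 (2.48) were higher as well, and C3 was 7.98-fold higher. Saa3 and Lcn2 were at least 15.0-fold and 7.33-fold higher. Krtap6-1 (-4.18), Klhl30 (-2.74), Mgp (-2.63) and Krt19 (-2.21) were lower. The array with ADSC medium alone, on which Krtap6-1 was also far above untreated cells, enters both of its differences. IL-17 target genes had a median of 2.19, above each of 10000 matched random lists, with 14 of 22 at least 2-fold higher. Collagen genes had a median of -0.30 and activation genes a median of -0.22, each below each of 10000 matched random lists. Antigen presentation genes had a median of -0.25, at percentile 0.25 of 10000 matched random lists. Glycolysis and hypoxia genes, at a median of 0.45 without medium, had one of -0.077 with it, at percentile 5.25 of 10000 matched random lists. Of their 21 measured members 14 were below 0. The rule counted 460 genes higher and 292 lower, but 57.6% of the higher genes rested on probes without a RefSeq accession. With RefSeq-matched probes alone, 203 genes were higher and 251 lower, against 723 and 171 with 75th percentile scaling and 687 and 180 with median scaling, and 76 and 22 with normexp background correction.

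Across 14480 genes above background on all 4 arrays, the IL17A differences with and without medium, which share no array, had a Pearson r of 0.425 and a Spearman rho of 0.298. That r was 0.376 with either scaling, 0.633 with normexp background correction, 0.645 with RefSeq-matched probes and 0.148 with no filter on dim probes. These are correlations across genes, which are not independent replicates. Of the 345 genes higher with IL17A alone, 109 were also at least 2-fold higher in the medium arrays, where independent lists would share 9.53. Of the 363 lower genes, 78 were lower again, where independent lists would share 6.37. With dim values at their bound, the median of the 345 genes was 1.43 where they were chosen and 0.55 between the medium arrays. That of the 363 genes was -1.35 where they were chosen and only -0.23 between the medium arrays. For ADSC medium against untreated, which uses the same untreated array, the 363 genes had a median of -1.06. High values on that array alone could thus account for part of the lower set.

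**Figure D2:**
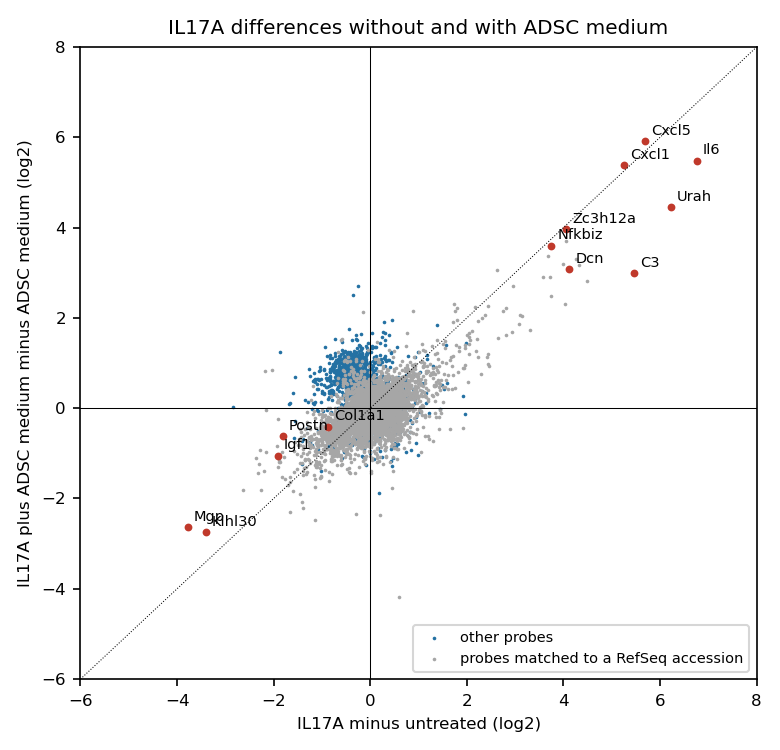
Log2 difference of IL17A against untreated (horizontal) and of IL17A plus ADSC medium against ADSC medium (vertical) per gene, grey for genes on a RefSeq-matched probe, blue for others and red for named genes, with the dotted line marking equal differences. Cxcl5 and Cxcl1 lay near the dotted line, Il6 below it at 6.76 and 5.48, and many blue points formed a separate cloud above the others.

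ADSC medium was set against untreated cells to describe the medium alone, across slides. The immediate early transcription factor gene Egr1 was 6.83-fold higher on the medium array, Fos was higher by 1.93 and the growth factor gene Areg by 1.94, and Egr3, dim in untreated cells, was at least 12.0-fold higher. Immediate early genes had a median of 1.03, above each of 10000 matched random lists, and 12 of 22 measured members were at least 2-fold higher. Cholesterol synthesis genes were lower, with Insig1 at -1.32, Fdps at -1.11, Nsdhl at -1.07 and Lss at -1.06. Their median was -0.76, below each of 10000 matched random lists, with 5 of 19 at least 2-fold lower. TGF-beta response genes had a median of 0.51, above each of 10000 matched random lists, although Tgfb2 itself was lower (-1.61). That median was 0.36 with normexp background correction and 0.39 with the mean of probes. Collagen genes had a median of -0.45, below each of 10000 matched random lists, with Col3a1 at -1.22 and Col6a3 at -1.09. The activation list had a median of 0.20, at percentile 99.74 of 10000 matched random lists, and 0.071 with genes above background on all 4 arrays. In that list Postn (1.17) and Timp1 (1.13) were higher and the PDGF receptor gene Pdgfrb (-1.25) lower. NF-kB feedback and inflammatory genes had a median of 0.24, at percentile 99.98 of 10000 matched random lists, with 15 of 22 above 0. Antigen presentation genes had a median of 0.40, above each of 10000 matched random lists, and 0.17 with normexp background correction. IL-17 target genes had a median of -0.23, at percentile 0.23 of 10000 matched random lists, which turned to 0.079 with no filter on dim probes.

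Single genes far apart on these arrays were Krtap6-1 (4.32), Sprr2h (3.29), Ccbe1 (3.24) and Dok7 (2.74) on the higher side. For Krtap6-1 the same medium array gave the large drop with IL17A in cells with medium. On the lower side were Cep126 (-4.59), Ranbp3l (-3.85), the heparin-binding growth factor gene Ptn (-3.64), the alkaline phosphatase gene Alpl (-3.24), Zfp141 (-3.18) and Mmp3 (-2.84). Otulinl and Serpinb2 were at least 37.8-fold and 15.8-fold higher and Plg at least 43.2-fold lower. The bounds of Plg here and for IL17A both rest on its level on the untreated array. Counts were 394 higher and 479 lower, against 346 and 278 with RefSeq-matched probes, 269 and 655 with 75th percentile scaling and 275 and 646 with median scaling, and 49 and 110 with normexp background correction. The medium and the slide cannot be told apart in this comparison.

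The medium was then compared in IL17A-treated cells, which addresses its effect during exposure to the cytokine. Saa3 was 8.63-fold lower with added medium, Lcn2 6.29-fold, the stromelysin gene Mmp3 5.42-fold and Il6 2.52-fold lower. Ccl11 was at least 3.70-fold and Cxcl2 at least 2.06-fold lower, as both were dim with added medium. C3 (-1.72), Ccl20 (-1.20), Ccl8 (-1.36) and the receptor gene Tlr4 (-1.37) were lower too, whereas Cxcl5 was at -0.92 and did not pass the 2-fold rule. The list of NF-kB feedback and inflammatory genes as a whole had a median of only -0.072, at percentile 5.45 of 10000 matched random lists. Of its 22 measured members 8 were above 0. IL-17 target genes had a median of -0.47, below each of 10000 matched random lists, and 6 of 24 were at least 2-fold lower. Even so, with both treatments Il6 remained 43.1-fold, Cxcl5 27.4-fold and Cxcl1 26.1-fold above untreated cells, and Saa3 at least 16.5-fold.

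Postn was 5.12-fold higher with added medium, Ccn2 2.58-fold and Timp1 2.06-fold, while the activation list as a whole had a median of 0.11, at percentile 92.2 of 10000 matched random lists, which ranged from 0.011 with median scaling to 0.34 with the mean of probes. Among collagen genes, lower values were measured, with Col3a1 at -1.54, Col6a3 at -1.49 and a list median of -0.19, at percentile 0.41 of 10000 matched random lists. That median was -0.050 with normexp background correction and -0.039 with the mean of probes. Against untreated cells, both treatments together gave a collagen median of -0.75, with Col6a3 at -1.92, Col1a2 at -1.49, Col3a1 at -1.19 and Col1a1 at -1.08. That comparison had 549 genes higher and 697 lower, led by Sprr2h (6.58) and Ccbe1 (5.54) on 1 side and Klhl30 (-5.40) and Ptn (-4.98) on the other. Cholesterol synthesis genes had a median of -0.69, below each of 10000 matched random lists, with Lss at -1.15 and Idi1 at -1.01. Fdps was at -1.22 and Nsdhl at -1.13 by their brightest probes, and another probe of each went the other way, at 0.59 and 0.12. Immediate early genes had a median of 0.60, above each of 10000 matched random lists, with Egr3 at least 6.17-fold higher, Egr1 at 2.47 and Egr2 at 1.69. TGF-beta response genes had a median of 0.49, above each of 10000 matched random lists, led by Pmepa1 (1.46). Glycolysis and hypoxia genes had a median of -0.29, below each of 10000 matched random lists, and antigen presentation genes one of 0.42, at percentile 99.95 of 10000 matched random lists, and 0.26 with normexp background correction. Other large differences were Serpinb2 (3.33), Lce1g (2.66), Lce1i (2.57) and Slc22a29 (2.48) on the higher side and Ranbp3l (-3.90), Ptn (-3.47), Col2a1 (-3.45) and Hlf (-3.10) on the lower side. Totals were 511 higher and 494 lower, against 227 and 329 with RefSeq-matched probes, 775 and 372 with 75th percentile scaling and 751 and 383 with median scaling, and 73 and 122 with normexp background correction. Between the medium differences with and without IL17A, 84 genes were at least 2-fold higher in both and 185 lower in both, where independent lists would share 12.09 and 14.2, and 13 went opposite ways. Slide and medium differ together here as well.

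**Figure D3:**
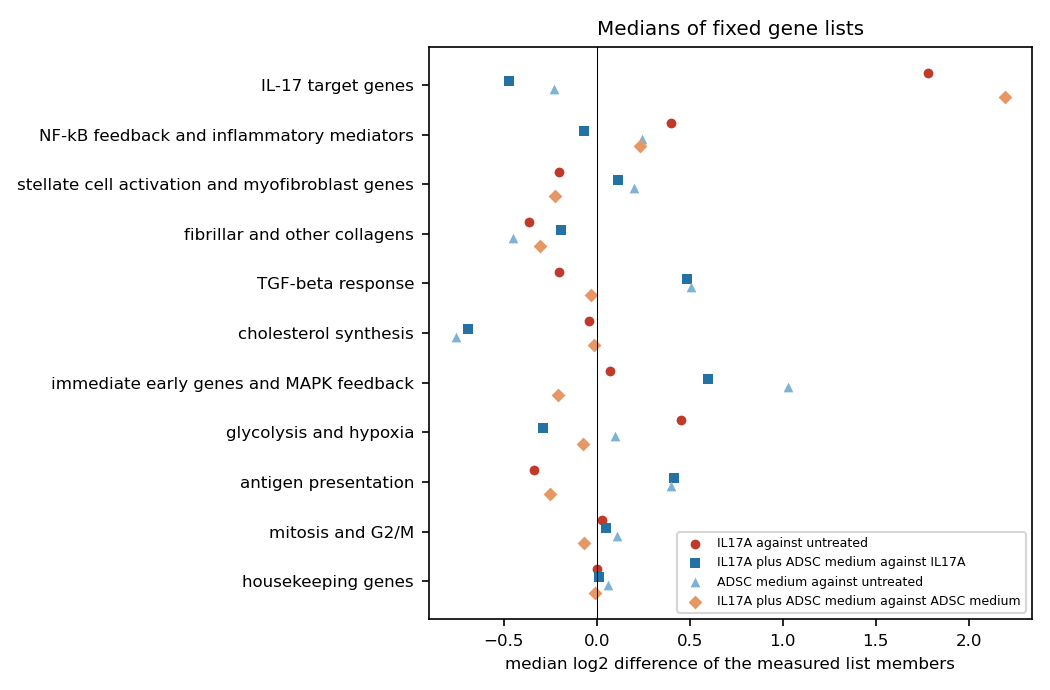
Median log2 difference (horizontal) of the measured members of 11 fixed gene lists (vertical) in 4 comparisons, 1 symbol each. IL-17 target genes lay at 1.78 and 2.19 for IL17A, and cholesterol synthesis genes at -0.76 and -0.69 for the medium.

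Genes higher with IL17A and at least 2-fold lower when medium was added, as Saa3, Lcn2, Il6, C3 and Mmp3 were, numbered 144 of 345. Mmp3 was lower by a similar amount without IL17A (-2.84, against -2.44 with it), and its IL17A difference was 2.16 with medium and 1.76 without. Independent lists would share 10.4, and simulated unchanged arrays with the larger of 2 noise levels gave a mean of 4.15. That noise came from the differences of differences, in which a difference between the slides cancels. The simulation therefore holds no slide effect, although adding medium was compared across slides. The IL17A array enters both differences, so the overlap is not independent of that array's own errors. With RefSeq-matched probes the number was 110 of 296, against 7.30 for independent lists. It was 50 when genes had to be above background on all 4 arrays and 17 with normexp background correction. Over the 345 genes the median share of the increase removed was 44.4%, with dim values held at the background limit, and 26.4% over the 219 of them above background on the untreated, IL17A and combined arrays, a subset chosen after the result was seen. In all, 145 stayed at least 2-fold above untreated cells with medium. The opposite pattern, lower with IL17A and higher with added medium, held for 40 genes, and for 22 with RefSeq-matched probes, 96 with 75th percentile scaling and 5 with normexp background correction. The covariance of the 2 differences was -0.0586, against -0.0241 in the same simulation, whereas their Pearson r was nearer 0, at -0.308 against -0.498.

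The difference of differences sets the IL17A response with medium against that without. For 16 IL-17 target genes above background on all 4 arrays its median was -0.17, at percentile 0.14 of random lists, with 11 below 0, although the list median itself was higher with medium (2.19) than without (1.78). The order of those list medians turned over with normexp background correction, at 1.04 with medium and 1.71 without, and with no filter on dim probes, at 1.39 and 1.82. NF-kB feedback and inflammatory genes had a median of -0.32 with 20 of 22 below 0, and glycolysis and hypoxia genes a median of -0.25. Collagen genes had a median of 0.18 and TGF-beta response genes 0.18. Over all genes, 808 differed by 1 or more upward and 595 downward, and 614 of the upward genes rested on probes without a RefSeq accession. When genes had to be above background on all 4 arrays the numbers were 535 and 227. With RefSeq-matched probes 198 were upward and 450 downward. The split tilted further upward with 75th percentile scaling, at 1345 upward and 198 downward, and with median scaling, at 1318 and 205. No such difference was tested, as a test would need replicates.

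An additive limma fit over the 4 arrays, with 1 residual degree of freedom, gave each treatment a test that assumes equal effects in both backgrounds. For IL17A, 393 genes rose and 587 fell at a Benjamini-Hochberg adjusted p below 0.05 among 15472 tested, and 212 of these changed at least 2-fold. Il6 rose by 6.12 (adjusted p = 0.000169 by limma), Cxcl5 by 5.80 (adjusted p = 2.93e-07 by limma) and Cxcl1 by 5.32 (adjusted p = 1.89e-07 by limma), each higher in both pairs of arrays. In simulated data 17.8% or 7.04% of the fit's calls were false, depending on how the noise was simulated. The simulated changes were 2.83-fold or 8-fold and equal with and without medium. These shares are therefore no error rate for the many smaller changes called here. Of 21 IL-17 target genes 16 rose, and 17 adjusted over the list alone, while 7 of 15 collagen genes fell, and 9 adjusted over the list alone. For the medium term, which carries the slide, 1496 genes rose and 1377 fell, and those that fell included all 19 tested cholesterol synthesis genes, and 19 adjusted over the list alone. Immediate early genes rose in 16 of 21 cases and fell in 2, and 19 rose when adjusted over the list alone. The totals were 165 for IL17A and 1210 for the medium with 75th percentile scaling, and 346 and 1415 with median scaling. Without a trend in the prior of the spread the fit called 0 genes for either term, at 1852 and 3340 genes with an unadjusted p under 0.05, and with no filter on dim probes it called 0 as well, at 2839 and 5515.

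The authors' deposited lists hold probe IDs without values, with 1 probe per gene. The list of probes up with IL17A over untreated cells has 861 entries, 494 of them at a log2 difference of 1 or more here and 317 of these also above background with IL17A, and 274 of the 345 genes past the 2-fold rule were in it. Il6, Urah, Cxcl5 and C3 were listed, as was Nos2, which was dim in untreated cells. The list held 16 of the fixed IL-17 target genes, Cxcl1 among them, but not Saa3 or Lcn2. The list of probes up with IL17A over IL17A plus medium has 1193 entries, 597 of them at a log2 difference of 1 or more here and 378 of these also above background with IL17A, and 320 of 494 genes past the rule were in it. It held Ranbp3l, Ptn, Mmp3, C3 and Il6, and also Unc93a, Bmf and Flt3, which were dim with both treatments. Of the listed probes, 35.3% and 29.0% were not well above background on either array of their comparison. The lists shared 325 probes.

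Markers of other cell types were counted to see what else the RNA might hold. Above background on all 4 arrays were 2 of 10 hepatocyte markers, 3 of 12 endothelial, 2 of 10 lymphocyte and 4 of 12 macrophage markers. The same held for 6 of 11 cholangiocyte and epithelial markers, 6 of 12 adipocyte, 5 of 10 mesothelial and portal fibroblast and 9 of 13 adipose stromal cell markers. Of all 26683 genes, 14480 were above background on all 4 arrays, so such counts alone do not point to another cell type. Some markers, such as Thy1 and Pdgfra, also stand in the activation list. The adipose stromal list had a median of 0.20 (at percentile 98.59 of 10000 matched random lists) for IL17A against untreated, 0.055 with normexp background correction. For medium against untreated its median was 0.23 (at percentile 95.88 of 10000 matched random lists), 0.086 with normexp background correction and 0.14 with the mean of probes, and it was -0.11 (at percentile 13.09 of 10000 matched random lists) for medium added to IL17A, but 0.12 with 75th percentile scaling and 0.11 with median scaling. The mesothelial and portal fibroblast list had a median of -0.55 (at percentile 0.035 of 10000 matched random lists) for IL17A in cells with medium, -0.11 with no filter on dim probes, and of -0.47 (at percentile 1.055 of 10000 matched random lists) for medium added to IL17A. The last median was -0.20 both with normexp background correction and with no filter. The cholangiocyte and epithelial list had a median of -0.50 (at percentile 0.25 of 10000 matched random lists) for IL17A in cells with medium, with 2 of 7 measured members at least 2-fold lower, and -0.073 with normexp background correction. The macrophage list, with 5 members, had a median of 0.59 (at percentile 98.54 of 10000 matched random lists) for both treatments against untreated. For IL17A against untreated its median was 0.093 (at percentile 57.4), with 2 of 6 members above background on at least 1 array at least 2-fold higher.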

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

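The alternative with RefSeq-matched probes only was chosen after the data were seen, and the others before. List medians of the IL-17 target, activation and collagen genes, and those of cholesterol synthesis and immediate early genes for the medium, kept their direction under the alternatives run, except the IL-17 target median for ADSC medium against untreated with no filter. The median of growth factors for IL17A plus medium against medium, which was near 0, reversed under 4 alternatives. Counts past the size rule moved with filter, threshold, background correction, scaling and the choice of probes. The larger moves of the main values, and the growth factor median, follow by setting. Smaller moves and those of other lists are left out. For instance, median scaling gave 751 genes higher for IL17A plus medium against IL17A and 687 for IL17A plus medium against medium. The cause was not tested except where the construction of the setting shows it. Here "both" means IL17A plus ADSC medium and "medium" means ADSC medium.

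With normexp background correction, whose offset shrinks differences of dim probes by construction, the genes past the rule numbered 97 higher and 66 lower for IL17A against untreated, 73 higher and 122 lower for both against IL17A, 49 higher and 110 lower for medium against untreated, 76 higher and 22 lower for both against medium, 128 higher and 177 lower for both against untreated. There, 17 genes were higher with IL17A and lower with added medium, 5 had the opposite pattern, 108 differences of differences were above the threshold, 23 were below it, the IL17A term of the limma fit called 489 genes, the IL17A differences correlated at 0.633, the medium differences correlated at 0.720. List medians there were -0.38 for IL-17 target genes, both against IL17A, -0.10 for IL-17 target genes, medium against untreated, 1.04 for IL-17 target genes, both against medium, 0.20 for stellate cell activation and myofibroblast genes, both against IL17A, -0.050 for fibrillar and other collagens, both against IL17A, -0.31 for fibrillar and other collagens, medium against untreated, 0.49 for immediate early genes and MAPK feedback, both against IL17A, 0.80 for immediate early genes and MAPK feedback, medium against untreated, -0.0028 for growth factors and secreted regulators, both against medium. When a gene had to be well above background on all 4 arrays, which tests fewer genes, the genes past the rule numbered 205 higher and 202 lower for IL17A against untreated, 218 higher and 256 lower for medium against untreated, 286 higher and 148 lower for both against medium, 330 higher and 426 lower for both against untreated. There, 50 genes were higher with IL17A and lower with added medium, 535 differences of differences were above the threshold, 227 were below it. List medians there were 0.071 for stellate cell activation and myofibroblast genes, medium against untreated. With no filter on dim probes and no bound, which adds dim genes, the genes past the rule numbered 969 higher and 1096 lower for IL17A against untreated, 1270 higher and 1221 lower for both against IL17A, 1111 higher and 1186 lower for medium against untreated, 1110 higher and 951 lower for both against medium, 1253 higher and 1412 lower for both against untreated. There, 438 genes were higher with IL17A and lower with added medium, 235 had the opposite pattern, 1966 differences of differences were above the threshold, 1607 were below it, the IL17A term of the limma fit called 0 genes, the medium term called 0, the IL17A differences correlated at 0.148, the medium differences correlated at 0.208. List medians there were 0.079 for IL-17 target genes, medium against untreated, 1.39 for IL-17 target genes, both against medium, 0.071 for stellate cell activation and myofibroblast genes, medium against untreated, -0.29 for fibrillar and other collagens, medium against untreated, -0.22 for growth factors and secreted regulators, both against medium. At the 1.5-fold threshold, by construction, the genes past the rule numbered 903 higher and 1037 lower for IL17A against untreated, 1428 higher and 1406 lower for both against IL17A, 1170 higher and 1280 lower for medium against untreated, 1211 higher and 947 lower for both against medium, 1508 higher and 1699 lower for both against untreated. There, 406 genes were higher with IL17A and lower with added medium, 307 had the opposite pattern, 1379 differences of differences were above the threshold, 1568 were below it. At the 4-fold threshold, by construction, the genes past the rule numbered 93 higher and 71 lower for IL17A against untreated, 51 higher and 77 lower for both against IL17A, 50 higher and 106 lower for medium against untreated, 92 higher and 37 lower for both against medium, 114 higher and 147 lower for both against untreated. There, 24 genes were higher with IL17A and lower with added medium, 1 had the opposite pattern, 108 differences of differences were above the threshold, 84 were below it. With scaling to the 75th percentile of each array the genes past the rule numbered 775 higher for both against IL17A, 723 higher and 171 lower for both against medium. There, 96 had the opposite pattern, 1345 differences of differences were above the threshold, 198 were below it, the IL17A term of the limma fit called 165 genes, the medium term called 1210. List medians there were 0.025 for stellate cell activation and myofibroblast genes, both against IL17A, 0.69 for immediate early genes and MAPK feedback, both against IL17A. With RefSeq-matched probes only the genes past the rule numbered 227 higher and 329 lower for both against IL17A, 278 lower for medium against untreated, 203 higher for both against medium. There, 22 had the opposite pattern, 198 differences of differences were above the threshold, the IL17A differences correlated at 0.645, the medium differences correlated at 0.663. List medians there were -0.11 for IL-17 target genes, medium against untreated. With scaling to the median the genes past the rule numbered 180 lower for both against medium. There, 95 had the opposite pattern, 1318 differences of differences were above the threshold, 205 were below it, the IL17A term of the limma fit called 346 genes, the medium term called 1415. List medians there were 0.011 for stellate cell activation and myofibroblast genes, both against IL17A, -0.36 for fibrillar and other collagens, medium against untreated. With the mean of all probes of a gene list medians were -0.093 for IL-17 target genes, medium against untreated, 0.34 for stellate cell activation and myofibroblast genes, both against IL17A, -0.039 for fibrillar and other collagens, both against IL17A, -0.64 for cholesterol synthesis, medium against untreated, -0.023 for growth factors and secreted regulators, both against medium. With list members at their bound list medians were -0.11 for IL-17 target genes, medium against untreated, 0.25 for stellate cell activation and myofibroblast genes, both against IL17A, -0.099 for growth factors and secreted regulators, both against medium. Without a trend in the prior of the spread the IL17A term of the limma fit called 0 genes, the medium term called 0.

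The additive fit paired the arrays of a slide for IL17A. No pair within a slide existed for the medium. Leaving out a replicate did not apply, and slide could not be fitted apart from the medium. Signal over background limits dim genes, for which the technical SD of a difference was 0.30.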

Other observations

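The tests on probe classes and exon positions, on how much of a difference chosen genes kept and on the subsets above background were written after the results were seen, and the others before.

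Of 4225 probes without a RefSeq accession and above background on all 4 arrays, 22.7% had a difference of differences of 1 or more, against 0.581% of 18759 RefSeq-matched probes. Over all probes without a RefSeq accession, the mean deviation from their own 4-array mean was 0.12 on the array with both treatments. It was -0.046 on the IL17A array and -0.11 on the medium array. The probes past 1 lay on average at 0.57, -0.36 and -0.33 on these arrays, but choosing them by that difference favours such values. Regulation of the genes these probes are named for is argued against for the 465 genes that also had a RefSeq-matched probe. Their 857 RefSeq-matched probes had a median difference of differences of -0.0096. Genes without such a probe could not be checked. Noise of dim probes is argued against as well, since RefSeq-matched probes of the same levels reached 1 only 0.0467 times as often. Unspliced RNA or DNA in the RNA samples may be the source, but with 0 columns of exon positions in the gene table used here, introns could not be told from exons on the mm9 positions that came with the probes.

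Cholesterol synthesis genes were lower and immediate early genes higher on both arrays with ADSC medium, the latter with a smaller median in the presence of IL17A. The GC content of the probes is argued against as the whole cause, as the list medians nearer 0 were still -0.68 and 0.58 after the trend on probe GC was removed. A slide or scan effect stays open, because 0 slides held arrays with and without medium. The design's own explanation, something in the conditioned medium, is untested for the same reason. Differences in culture or RNA handling between the medium conditions were not tested either.

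Genes higher with IL17A and lower with added medium, such as Saa3 and Lcn2, have as a set open explanations, a lowering of the IL17A response by the medium among them, but not for Mmp3, which was lower alike without IL17A (-2.84) and with it (-2.44). Chance values of the shared IL17A array stay open. The 144 genes outnumbered the mean of 4.15 in simulated unchanged arrays, but only under noise estimated without a replicate culture and without a slide effect. An equal drop with and without IL17A stays open too, and the medians over the set, -0.057 for IL17A between the medium arrays and 0.13 for medium against untreated, measure little, because arrays that enter them also chose the genes and 56 and 62 of the genes were dim on both arrays compared. Over the 54 and 51 genes above background on both arrays they were 0.50 and -0.45, still subject to the choice of genes. Genes picked for a large difference on 1 pair of arrays may also shrink on any other pair, which stays open, as those picked on the medium arrays kept 31.3% without medium and those picked without medium kept 38.5% with it, or 63.5% and 44.2% with RefSeq-matched probes.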
